A study of Homo sapiens with 8 samples.

How the data were processed

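Total RNA from 2 human colon cancer cell lines was profiled on Affymetrix GeneChip U133 Plus 2 arrays. LS180 is described by the submitters as having microsatellite instability (MSI+), a loss of mismatch repair that leaves insertions and deletions in short repeats, and SW480 as lacking it (MSI-). The series holds 8 arrays, 1 per line and treatment. The treatments were none, emetine at 100 ug/mL for 8 h, caffeine at 10 mM for 4 h followed by actinomycin D at 2 ug/mL for 4 h, and the same sequence with caffeine at 10 mM kept in the medium during actinomycin D. Per the labels' protocols, RNA was extracted with TRIZOL and labelled with biotin, and the cells grew in DMEM with fetal bovine serum.

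The deposited values are probe set intensities on a linear scale, and the trimmed mean of each array lies near 500.1, so the authors had scaled the arrays to equal trimmed means. The algorithm that summarised probes into these intensity values is not given in the sources used here, and no detection calls were used here. The table holds 54675 probe sets, of which 62 are array controls that were left out of every test. The platform annotation names 1 gene symbol for 41097 probe sets, several for 1801 and none for 11777. Of the 1-symbol probe sets, 41043 were matched to current symbols through their gene number. For MIRLET7D, MIR34A, MIR146A, SCARNA17 and RNA45SN5 the symbol is the annotation of a probe set. Whether that probe set reads the small or ribosomal RNA itself was not examined. No coordinates are printed, because the sources name no genome build.

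Array medians ranged from 78.8 to 104.6, a ratio of 1.33, above the bound of 1.25. Each array was therefore scaled to the common median, and log2(value + 27.1) was taken, the pseudocount being the 25th percentile of all values. Fold changes are on that scale and understate changes of dim probe sets. The upper 50% of probe sets by mean log2 value were kept (27307), 22839 of these had 1 symbol, and the probe set with the highest mean stood for each gene, which gave 12369 genes. The number of arrays limits the precision.

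Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over the 12369 genes and a threshold of 0.05. Emetine against untreated, caffeine kept against caffeine removed during actinomycin D, and caffeine then actinomycin D against untreated were fitted on all 8 arrays with cell line as a block, since the same lines were used in each treatment. The pairing comes from the cell line named in the labels. A further fit took emetine with untreated and caffeine kept with caffeine removed, in each line, as 4 pairs. LS180 was compared with SW480 with treatment as a block. These fits have 3 residual degrees of freedom, and the test of whether the response to the inhibitors differed between lines has 2. There is 1 array per group, so differences within a line have no replicate check. The labels do not say whether arrays came from separate cultures, so p-values measure only the spread between lines and treatments. That spread was over all 4 conditions for the first 3 comparisons and the line comparison, and between the 4 pairs for the pair fit. For the line difference in response, it was the change of the gap between lines within 2 sets of arrays. These sets were untreated with caffeine then actinomycin D, and emetine with caffeine kept. That fit had no block for the pairs, so its p-values do not measure how well the inhibitor settings agreed.

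The study looked for transcripts with truncating mutations, which nonsense-mediated decay (NMD) removes and which rise when that decay is blocked. A rule of size therefore counted genes at least 1.5-fold higher in both inhibitor settings in 1 line and under 1.2-fold higher in both in the other. Its count was set against 10000 re-pairings of the settings between genes of like level. The 26 gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Within a line, a list's median was placed among 10000 random lists matched on mean level. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

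For each comparison the text names the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with the same direction in every pair. Where fewer than 5 passed, the 10 genes with the largest smallest-of-the-pairs difference were taken and are said not to pass. Up to 4 members with the largest absolute difference were taken from a list. This rule, the scaling bound, the rule of size, the gene lists and the tests of the comparisons were set before the data were examined, and members named beyond it are identified as such. Each fit was tested on simulated data with 200 changed genes. For emetine, 4% of 2-fold changes, 72% of 4-fold changes and 96% of 8-fold changes were recovered, with 9 false calls among the 12369 genes. Caffeine kept gave 4%, 80% and 100%, the 4 pairs 54%, 100% and 100%, and the line difference in response 0%, 12% and 60%. Alternatives covered the scaling, the pseudocount, the filter, the choice of probe set, the variance model, the threshold, the block, the arrays in the fit and leaving out each array.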

Results

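Gene expression was compared between LS180 and SW480 cells under 4 conditions: untreated, emetine, caffeine followed by actinomycin D, and the same with caffeine kept. Emetine stops translation, on which NMD depends, caffeine blocks the phosphorylation of the NMD factor UPF1, and actinomycin D stops transcription. Each of the 8 groups was 1 array, and 12369 genes were tested. The ratio of the 3-prime to the 5-prime actin control was 3.66 in untreated LS180 and 2.96 in untreated SW480. It lay between 1.47 and 2.54 on the treated arrays. Whatever this ratio reflects cannot be told apart from treatment where treated arrays were compared with untreated ones. The poly-A control transcripts were 6.91-fold brighter in LS180 and 5.98-fold brighter in SW480 on the array of caffeine then actinomycin D than on the untreated array. They differed by 1.07-fold in LS180 and 1.08-fold in SW480 between emetine and untreated, and by 1.08-fold and 0.928-fold between caffeine kept and removed.

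With emetine 38 genes rose and 8 fell, each in the same direction in both lines. The chemokine gene CCL20 (gene 6364) rose most, by 7.29 ± 0.63 (SE) on the log2 scale, 157-fold (adjusted p = 0.00241), with 6.26 in LS180 and 8.33 in SW480. CXCL2, another chemokine gene, rose 83.8-fold, with 3.65 in LS180 and 9.13 in SW480. The nuclear receptor genes NR4A3 and NR4A1 rose 72.2-fold (4.17 and 8.17) and 15.5-fold (2.64 and 5.26). ATF3 rose 31.7-fold and FOS 19.6-fold, both transcription factor genes of the early stress response. CYP1A1, NEURL3, TNFAIP3, an inhibitor of NF-kB signalling, and GEM rose 46.3-fold, 18.7-fold, 18.8-fold and 16.7-fold. Their log2 values in LS180 and SW480 were 7.70 and 3.36 for CYP1A1, 4.67 and 3.77 for NEURL3, 2.87 and 5.60 for TNFAIP3, and 2.52 and 5.61 for GEM. All 8 genes that fell are named here: ZC3HAV1 fell by 3.44 ± 0.38, BRI3BP by 3.33 ± 0.55, CASTOR2 by 2.96 ± 0.43, ATL3 by 2.89 ± 0.47, MAT2A by 2.67 ± 0.44, NACC2 by 2.38 ± 0.38, SUMF1 by 2.34 ± 0.37 and TNFRSF10D by 2.25 ± 0.38. A further probe set of NACC2 and one of TNFRSF10D lay the other way, at 0.40 and 0.58, and further ones reached only −0.29 for ZC3HAV1, −0.58 for ATL3 and −1.11 for MAT2A.

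The count of 46 genes in limma was 7 with arrays centred on the tested genes, 7 as deposited and 9 after quantile normalization, all of them among the 46, and 0 without the block. It was 1 without the untreated SW480 array, 6 without the untreated LS180 array, 13 without the SW480 emetine array, and 111 without either array of caffeine then actinomycin D. CCL20, ATF3, FOS, NEURL3 and ZC3HAV1 passed under all 3 other scalings, while CXCL2, NR4A3, NR4A1, CYP1A1, TNFAIP3, GEM and the other 7 genes that fell passed under none. With 1 of the 8 arrays left out in turn, CCL20 passed in 8 of 8, ATF3 in 7, and each gene that fell in 4 or 5.

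Immediate early genes, which are induced without new protein synthesis, lay higher with emetine in 34 of 34 measured members, with a median of 2.32 on the log2 scale. Of these, 7 rose over all genes and 27 when adjusted over the list alone (camera adjusted p = 4.17e-30; adjusted p = 0.0594 with an estimated correlation). NF-kB target genes were above 0 in 22 of 22, 4 rose over all genes and 19 adjusted over the list alone, with a median of 2.31 (camera adjusted p = 3.18e-22; adjusted p = 0.262 with an estimated correlation). CXCL8 and CXCL3 of that list did not pass, at 5.14 ± 1.03 and 4.83 ± 0.97. Targets of cAMP and CREB signalling were above 0 in 14 of 14, 4 rose and 13 when adjusted over the list alone, with a median of 3.37 (camera adjusted p = 4.5e-19; adjusted p = 0.123 with an estimated correlation). NR4A2 (4.91 ± 1.18) and FOSB (4.34 ± 0.76) did not pass.

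Transcripts known as natural NMD targets lay higher with emetine, with a median of 0.37 over 30 members. ATF3, GADD45B (13.3-fold) and DDIT3 (12.3-fold) rose over all genes and 5 rose when adjusted over the list alone (camera adjusted p = 5.98e-05; adjusted p = 0.262 with an estimated correlation). These 3 also encode stress response proteins. GADD45B, DDIT3 and H4C8, a histone gene, passed under none of the 3 other scalings and in 5 of 8 fits with 1 array left out. Histone genes had a median of 0.92 over 18 members; H4C8 rose 9.94-fold, and 5 rose when adjusted over the list alone (camera adjusted p = 3.83e-05; adjusted p = 0.262 with an estimated correlation). Zinc finger genes with short-lived mRNA had a median of 0.56 over 69 members; none rose over all genes and 9 did when adjusted over the list alone (camera adjusted p = 7.29e-08; adjusted p = 0.262 with an estimated correlation). ZNF226 (2.11 ± 0.58) and ZNF184 (2.04 ± 0.38) had the largest differences of that list. Splicing regulators with poison exons had a median of 0.16 over 29, with CLK4 at 1.95 ± 0.38 and CLK1 at 1.46 ± 0.54; none rose over all genes, and 1 did when adjusted over the list alone (camera adjusted p = 0.0251; adjusted p = 0.649 with an estimated correlation). The other 19 lists gave adjusted p from 0.0801 to 0.918. The lowest was that of the integrated stress response, with a median of −0.06, a mean of 0.49 and a test direction upward, 3 members past over all genes and 6 adjusted over the list alone.

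**Figure D1:**
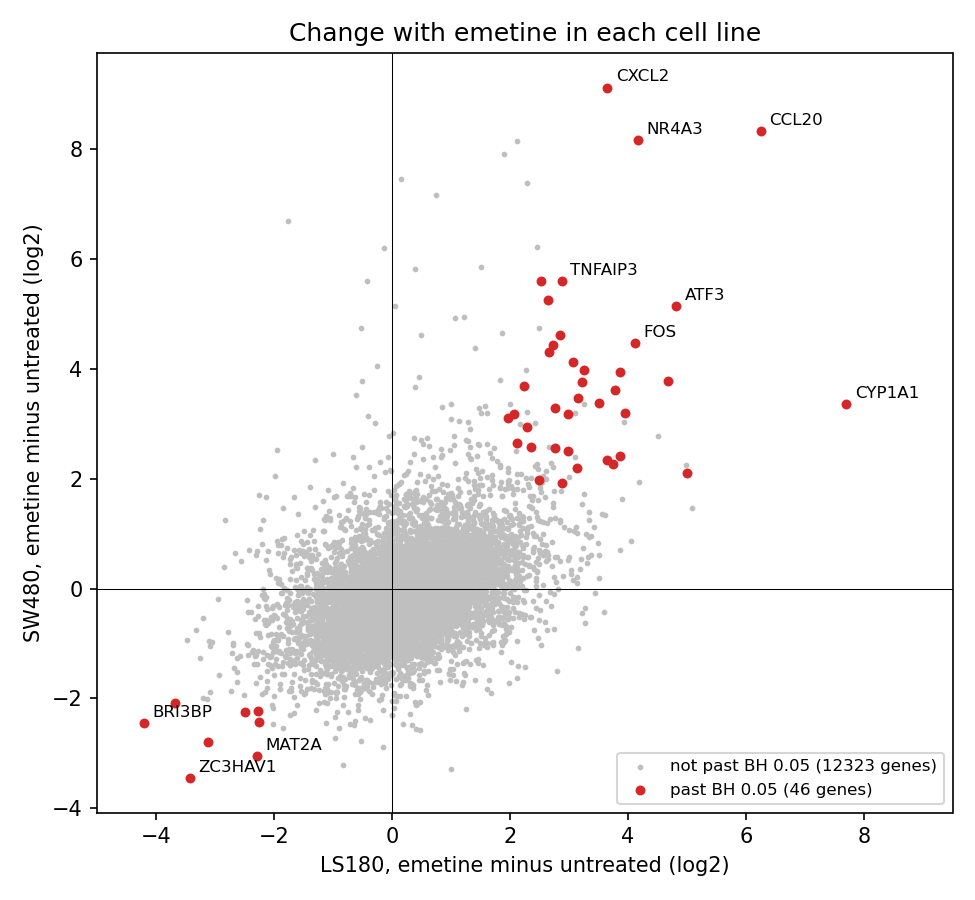
Log2 difference between emetine and untreated for each of 12369 genes, LS180 on the x axis and SW480 on the y axis, with 1 array per condition. Red points are the 46 genes past the threshold; CCL20 lies at 6.26 in LS180 and 8.33 in SW480, and ZC3HAV1 at −3.43 and −3.45.

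Keeping caffeine during actinomycin D left PPP1R15A, CLK1 and DDIT3 higher in both lines, with no gene past the threshold. PPP1R15A (gene 23645), which encodes a phosphatase subunit of the stress response, differed by 3.14 ± 0.38 on the log2 scale, 8.84-fold (adjusted p = 0.106). CLK1, a kinase of splicing factors, differed by 3.64 ± 0.54 and DDIT3 by 2.99 ± 0.45. ZNF408, IFRD1, ARID5B, ZC3H4, FOS, CDKN2AIP and KANSL2 lay between 2.35 (KANSL2) and 2.90 (ZNF408). In the other direction the probe set annotated to SCARNA17, the gene of a small RNA of the Cajal body, differed by −2.39 ± 0.41. That annotated to the ribosomal RNA precursor RNA45SN5 differed by −1.80 ± 0.40. A further RNA45SN5 probe set gave −0.95. HPS6, LINC01569, CIMIP2A, PAIP2B, DOC2A, ZBTB43, CD300LB and FKBPL lay between −1.82 (HPS6) and −1.19 (CD300LB), and of 4 ZBTB43 probe sets 1 lay above 0. In limma 0 genes passed, and 402 had an unadjusted p below 0.05, 337 higher and 65 lower. The count was 257 when only the 4 arrays of the comparison were fitted, and 1 without either SW480 actinomycin D array.

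Immediate early genes lay higher with caffeine kept in 29 of 34 members, with a median of 0.97. None passed over all genes, and 4 did when adjusted over the list alone (camera adjusted p = 1.99e-18; adjusted p = 0.122 with an estimated correlation). KLF10 (2.73 ± 0.52) and DUSP5 (2.47 ± 0.51) had the largest differences. Known NMD targets had a median of 0.21 over 30; none passed over all genes and 3 when adjusted over the list alone (camera adjusted p = 1.88e-05; adjusted p = 0.381 with an estimated correlation). Host transcripts of small nucleolar RNAs, several of which are NMD targets, had a median of 0.68 over 7, with GAS5 at 0.68 ± 0.43 and TAF1D at 1.37 ± 0.52; none passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0141; adjusted p = 0.381 with an estimated correlation). The cAMP and CREB targets had a median of 0.62, with none past over all genes and 2 adjusted over the list alone, PDE4D at 1.86 ± 0.48 (camera adjusted p = 2.04e-05; adjusted p = 0.381 with an estimated correlation). Genes of the integrated stress response had a median of 0.07, with none past over all genes and 2 adjusted over the list alone, DDIT4 at 1.48 ± 0.47 (camera adjusted p = 0.000102; adjusted p = 0.631 with an estimated correlation). Relative to all genes, their median was −0.01 in LS180 and 0.37 in SW480. Wnt and beta-catenin targets had a median of 0.38, MYC at 1.76 ± 0.77 and ZNRF3 at 1.64 ± 0.47, and none past over all genes or adjusted over the list alone (camera adjusted p = 0.000126; adjusted p = 0.483 with an estimated correlation). The zinc finger list had a median of 0.09, again with none past over all genes or adjusted over the list alone (camera adjusted p = 0.0141; adjusted p = 0.631 with an estimated correlation). The other 19 lists gave adjusted p from 0.114 to 0.866.

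Caffeine followed by actinomycin D lowered 220 genes and raised 4 against untreated cells. No array had caffeine alone or actinomycin D alone, so the share of each drug in these changes cannot be told apart. The median of all genes moved by −0.14 on the log2 scale, and folds in the next sentences are relative to it. PPP1R10 (gene 5514), a nuclear phosphatase subunit, fell 28.3-fold (adjusted p = 0.00378). LCMT2, TRIB1 and the death-domain adaptor FADD fell 19.7-fold, 18.3-fold and 17.3-fold, and the log2 difference of GTF3C4 was −4.46 before that median is taken off. RPUSD2, ZC3H4, MIRLET7D, IMP3 and EBLN2 fell 15.0-fold, 14.3-fold, 14.1-fold, 13.2-fold and 11.9-fold. The MIRLET7D value is that of a probe set annotated to this microRNA gene. Of the 4 genes that rose, TNFSF10, a death receptor ligand, rose 3.94-fold, TMEM35A 4.06-fold and LMNTD2-AS1 4.63-fold. The other was APOBEC3D, outside the rule for named genes and named after its values were seen, with a log2 difference of 2.32 ± 0.50. SLC6A17, EREG, ZDHHC20, TPM4, MUC2, RYBP and POU3F1 lay higher without passing, from 3.42-fold (TPM4) to 4.35-fold (SLC6A17). Of their probe sets, 1 of 2 for EREG and 1 of 4 for RYBP lay below 0. A further probe set of GTF3C4 gave only −0.37 and one of TNFSF10 only 0.66.

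With every array centred on the tested genes the median of all genes was 0.14, and 25 genes fell and 0 rose; 29 fell after quantile normalization and 44 as deposited. The count was 0 without the block and 0 without either untreated array, 63 without the LS180 array of caffeine then actinomycin D, and 96 without the SW480 one. Of the falls named above, EBLN2 passed under none of the 3 other scalings, GTF3C4 under 2 and the rest under all 3, and each passed in 6 of 8 fits with 1 array left out. None of the 4 rises passed under another scaling; LMNTD2-AS1 passed in 4 of 8 fits with 1 array left out, and TMEM35A, TNFSF10 and APOBEC3D in 2. The labels name no batch or hybridisation day. The poly-A controls were brighter on these arrays than on the untreated ones in both lines, while the hybridisation controls went from 2400 to 4441 in LS180 and from 4959 to 3495 in SW480. A difference in preparation of that kind cannot be told apart from the treatment here.

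Wnt and beta-catenin targets lay 1.70 below the median of all genes after caffeine and actinomycin D. AXIN2 fell by 3.38 ± 0.37 and BAMBI by 2.93 ± 0.40; 4 of 20 fell over all genes and 10 when adjusted over the list alone, where 1 rose (camera adjusted p = 2.85e-05; adjusted p = 0.554 with an estimated correlation). MYC, at −3.42 ± 0.77, did not pass. Immediate early genes lay 1.17 below that median; 4 of 34 fell over all genes, DUSP1 and DUSP6 among them, and 17 when adjusted over the list alone, where 2 rose (camera adjusted p = 3.55e-05; adjusted p = 0.554 with an estimated correlation). Of the zinc finger list 7 of 69 fell, including ZNF217, ZNF416 and ZNF12, and 13 when adjusted over the list alone, where 1 rose (camera adjusted p = 0.000134; adjusted p = 0.554 with an estimated correlation). Cell cycle genes, among them CDC25A (−2.15 ± 0.68) and CCNE1 (−1.92 ± 0.59), lay 0.51 below the median, with none past over all genes or adjusted over the list alone (camera adjusted p = 0.00694; adjusted p = 0.925 with an estimated correlation). NMD factors lay 0.46 below it; SMG8 fell 5.65-fold, 1 of 9 over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0454; adjusted p = 0.925 with an estimated correlation). Goblet and secretory markers lay 0.28 above it, with none past over all genes and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0205; adjusted p = 0.554 with an estimated correlation); this call was lost under each other scaling. Of the members that fell, AXIN2 passed under all 3 other scalings, BAMBI and SMG8 under 1, and DUSP1, DUSP6, ZNF217, ZNF416 and ZNF12 under none. The other 20 lists gave adjusted p from 0.119 to 0.939.

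**Figure D2:**
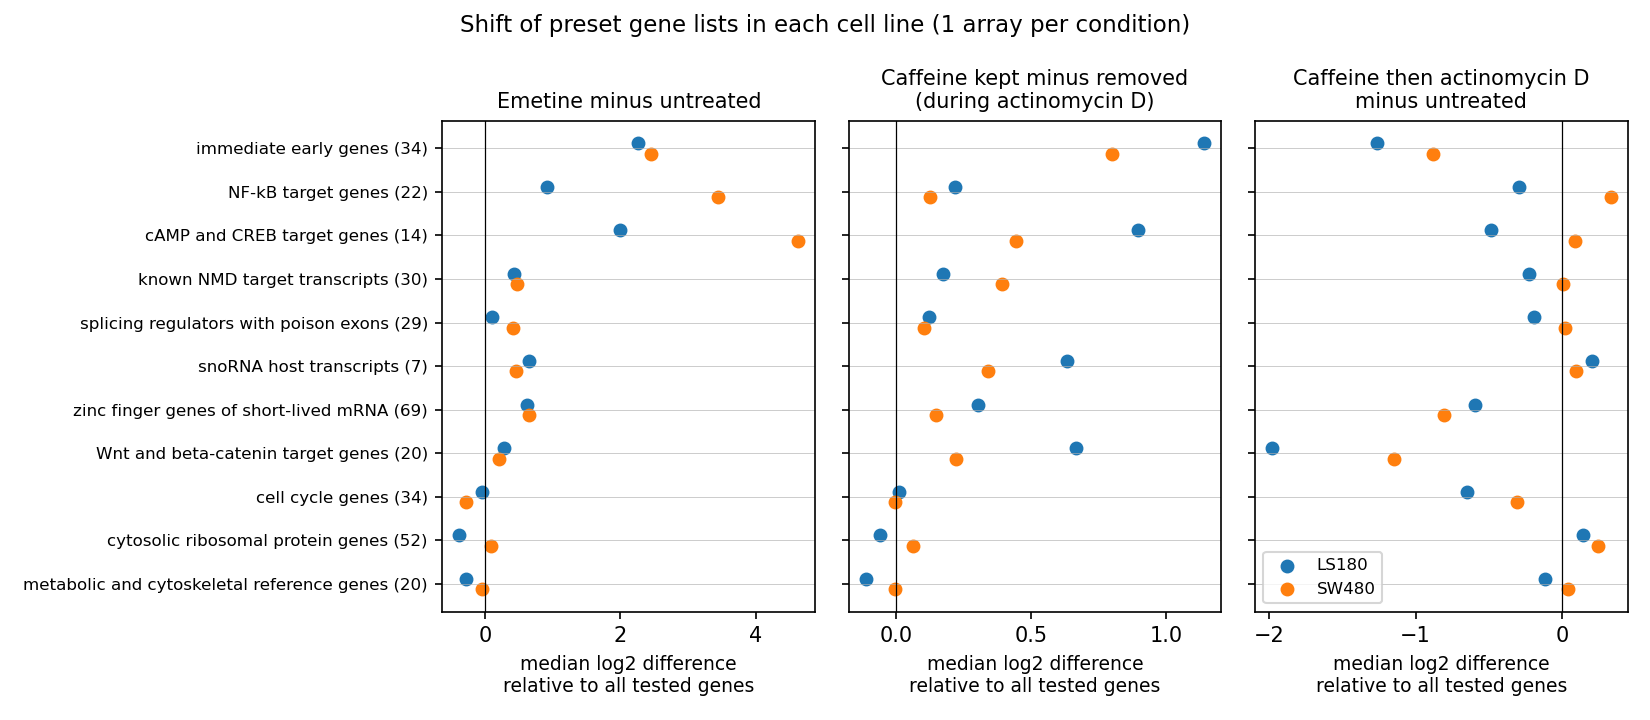
Median log2 difference of 11 preset gene lists relative to the median of all tested genes, in LS180 (blue) and SW480 (orange), for emetine, caffeine kept and caffeine then actinomycin D; the 3 panels have different x scales, the number of measured genes is in parentheses, and each point compares 2 arrays. For NF-kB targets the emetine values are 0.91 in LS180 and 3.44 in SW480.

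Across all 4 pairs of an inhibitor array (emetine, or caffeine kept) and its comparison array, 25 genes rose, PPP1R15A, FOS and DDIT3 among them. Whether blocked NMD accounts for these rises was not tested. PPP1R15A rose by 3.42 ± 0.23 on the log2 scale, 10.7-fold (adjusted p = 0.00203), and by at least 3.07 in each pair. FOS rose 10.3-fold and DDIT3, the transcription factor CHOP, 9.89-fold. GADD45B, EFNA1, KLF10, CITED2, IRF1, BHLHE40 and ARID5B rose between 5.07-fold (ARID5B) and 8.29-fold (GADD45B). The 4 GADD45B probe sets ranged from 0.78 to 3.57 on the log2 scale. The single gene that fell was RNA45SN5, by 1.65 ± 0.24, with a further probe set at −0.72. It no longer passed under any of the 3 other scalings (adjusted p from 0.0678 to 0.101) or with any 1 of the 8 arrays left out (0.0676 to 0.185). The 18S ribosomal RNA control signal went from 10894 to 9984 in LS180 and from 3948 to 818 in SW480 with emetine, and from 1389 to 2939 and from 2316 to 845 with caffeine kept. PALM2, FGF6, ZG16B, FITM2, MIR34A, SIGLEC15, ZMYND10, PDIA6 and CLDN2 lay lower in all 4 pairs without passing, from −1.30 (FGF6) to −0.64 (CLDN2). In limma 25 genes rose and 1 fell. By size alone, 153 genes were at least 1.5-fold higher in every pair, against 6.07 if the pairs were independent, and 10 were lower. The count of 26 became 2 with centred arrays, 5 as deposited, 7 after quantile normalization and 0 without the block, each count among the 26. It was 4 without either LS180 array of the emetine pair, 12 without either SW480 one, and 11 without either SW480 array of the caffeine pair. PPP1R15A and DDIT3 passed under all 3 other scalings and in 8 of 8 fits with 1 array left out. Leaving out either array of a pair removes that pair, so these 8 fits are 4 distinct ones. ARID5B passed under 1 other scaling, and FOS, GADD45B, EFNA1, KLF10, CITED2, IRF1 and BHLHE40 under none. With 1 array left out, FOS, KLF10, BHLHE40 and ARID5B passed in 6 of 8 fits, GADD45B in 4, EFNA1 and IRF1 in 2, and CITED2 in 0.

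Known NMD targets lay higher over the 4 pairs, with a median of 0.28 over 30. DDIT3 and GADD45B rose over all genes and 6 when adjusted over the list alone (camera adjusted p = 1.2e-05; adjusted p = 0.503 with an estimated correlation). Among splicing regulators, CLK4, a kinase of splicing factors, rose by 1.86 ± 0.21, 1 of 29 over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0152; adjusted p = 0.539 with an estimated correlation). CLK4 passed under 2 of the 3 other scalings and in 2 of 8 fits with 1 array left out, of which 4 are distinct. Immediate early genes lay 1.55 above the median of all genes, with 4 of 34 past over all genes and 27 adjusted over the list alone (camera adjusted p = 3.16e-25; adjusted p = 0.503 with an estimated correlation). The cAMP and CREB targets had a median of 2.18, with 2 of 14 past over all genes and 10 adjusted over the list alone (camera adjusted p = 1.35e-11; adjusted p = 0.503 with an estimated correlation). NF-kB targets had a median of 1.28, with none past over all genes and 6 adjusted over the list alone (camera adjusted p = 2.34e-09; adjusted p = 0.525 with an estimated correlation). The zinc finger list had a median of 0.33 and the Wnt list of 0.35, each with none past over all genes and 1 adjusted over the list alone (camera adjusted p = 1.06e-07 and 0.00158; adjusted p = 0.503 with an estimated correlation for each). Histone genes had a median of 0.35, with none past over all genes or adjusted over the list alone (camera adjusted p = 0.0152; adjusted p = 0.539 with an estimated correlation), and the call was lost as deposited. The stress response list, 2 of 29 past over all genes and 5 adjusted over the list alone, and p53 targets, 0 of 24 and 4 adjusted over the list alone, had medians of 0.04 (camera adjusted p = 0.0247 and 0.0492; adjusted p = 0.526 with an estimated correlation for each). With centred arrays both medians were −0.02 and the call of the stress response list was lost, and as deposited both calls were lost. The other 16 lists gave adjusted p from 0.0672 to 0.830.

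Across genes, the log2 change with emetine in LS180 correlated with that in SW480 at r = 0.449, and the change with caffeine kept at 0.257. Emetine against caffeine kept gave r = 0.192 in LS180 and 0.152 in SW480. These 4 pairs share no array, and genes are not independent replicates. At least 2-fold higher with emetine were 1879 genes in LS180, 706 in SW480 and 357 in both, against 107 if independent. With caffeine kept the numbers were 588, 601 and 165, against 28.6. At least 2-fold lower were 725, 968 and 229 with emetine, against 56.7. With caffeine kept 543, 177 and 11 were lower, against 7.77. The count in both lines was 5.78 times that if independent for rises and 1.42 times for falls with caffeine kept. With emetine it was 3.33 times for rises and 4.04 times for falls. Falls thus agreed less between the lines than rises with caffeine kept, but not with emetine. The median of all genes was 0.17 in LS180 and −0.23 in SW480 with emetine, and −0.22 and 0.06 with caffeine kept, which moves these counts.

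The lines differed in their epithelial state. In LS180 the goblet cell genes AGR2 (gene 10551) and TFF3 were higher by 9.52 ± 0.30 and 7.73 ± 0.28 on the log2 scale (adjusted p = 1.65e-07 for each). LGALS4, PIGR, which carries immunoglobulin across epithelia, MAGEA6, RAB25, GPA33, TFF1, S100P and CEACAM5 were higher by 7.31 (CEACAM5) to 8.80 (LGALS4). In SW480 the keratin genes KRT23 (gene 25984) and KRT5 were higher, with LS180 minus SW480 at −9.20 ± 0.33 and −8.41 ± 0.32. SLC2A3, a glucose transporter, PRF1, RGCC, VIM, APOBEC3G, TGM2, AKAP12 and NXN lay between −8.86 (SLC2A3) and −6.99 (NXN), with a further RGCC probe set at −0.94. Over the 4 conditions 2533 genes were higher in LS180 and 2212 in SW480, and 2452 and 2164 of them had the same direction in all 4 conditions. These are 1 line each, so the test is about these cultures and not about MSI status.

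Goblet and secretory markers were higher in LS180 in 19 of 22 and lower in 2, and the same when adjusted over the list alone, with a median of 4.06 (camera adjusted p = 2.6e-10; adjusted p = 0.113 with an estimated correlation). Enterocyte and colon epithelium markers, such as CDH17 (7.29 ± 0.37), were higher in 15 of 21 and in 15 when adjusted over the list alone, where 1 was lower, with a median of 3.17 (camera adjusted p = 2.77e-07; adjusted p = 0.113 with an estimated correlation). Of mesenchymal markers 7 of 12 were lower in LS180 and 7 when adjusted over the list alone, among them VIM, FN1 at −5.39 ± 0.47 and ZEB1 at −3.08 ± 0.33 (camera adjusted p = 0.00379; adjusted p = 0.395 with an estimated correlation). Immediate early genes were lower in LS180 in 18 of 34 and in 19 when adjusted over the list alone, with DUSP6 at −4.21 ± 0.30 (camera adjusted p = 1.15e-05; adjusted p = 0.238 with an estimated correlation). NF-kB targets were lower in 11 of 22 and in 13 when adjusted over the list alone, with TNFAIP2 at −4.20 ± 0.35 (camera adjusted p = 0.00184; adjusted p = 0.746 with an estimated correlation). Histone genes were lower in 10 of 18 and higher in 1, and lower in 12 and higher in 1 when adjusted over the list alone, with H2BC4 at −3.18 ± 0.42 (camera adjusted p = 0.00184; adjusted p = 0.447 with an estimated correlation). Cell cycle genes were lower in 14 of 34 and higher in 1, and lower in 16 and higher in 3 when adjusted over the list alone, with CCNE2 at −2.40 ± 0.32 (camera adjusted p = 0.00443; adjusted p = 0.784 with an estimated correlation). Xenobiotic metabolism genes, with AKR1B10 at 4.07 ± 0.30, were higher in 10 of 19 and lower in 1, and higher in 11 and lower in 2 when adjusted over the list alone (camera adjusted p = 0.0268; adjusted p = 0.746 with an estimated correlation), a call lost as deposited. The other 18 lists gave adjusted p from 0.0678 to 0.970.

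The search for transcripts kept by NMD inhibition in the MSI+ line asks whether the response differed between lines. No gene passed. MARCKS, a substrate of protein kinase C, responded more in LS180 by 3.36 ± 0.73 on the log2 scale, followed by SLC22A14, COX4I2, TERT and PRR29 between 2.23 (PRR29) and 2.74 (SLC22A14). ARIH2OS, PPARGC1A, SLIRP-OT1, RFX5 and VAV3 lay between 1.83 (VAV3) and 2.18 (ARIH2OS). RASD1 responded more in SW480, at −3.05 ± 0.74, as did NOG, MIR146A, UTS2R, TSPEAR-AS2, BAIAP2L2, ZBTB47, MYH13, DIO3 and ZNF420 (−1.85 ± 0.81), and 1 of 3 ZBTB47 probe sets lay the other way and 1 of 2 for TERT gave 0.02. In limma 0 genes passed and 202 had an unadjusted p below 0.05, 107 higher and 95 lower. The count was 4 without either array of caffeine then actinomycin D and 1 without either untreated array.

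By the rule of size, 95 genes were higher in both inhibitor settings in LS180 only and 50 in SW480 only. Re-pairing the settings between genes of like level gave 80 to 113 and 31 to 53, so chance agreement may account for both counts. The emetine part of the rule was met by 2046 genes for LS180 and 397 for SW480, the caffeine part by 514 and 878. The median of all genes moved the same way as these counts. It was 0.17 in LS180 and −0.23 in SW480 with emetine, and −0.22 and 0.06 with caffeine kept. With arrays centred on the tested genes, 86 genes were LS180-only and 56 SW480-only. The leading LS180 genes were SLC22A14 (2.96-fold with emetine and 2.23-fold with caffeine kept), COX4I2, PRR29, VAV3, PARTICL, ADGRG2, UBALD1, MRC2, EHHADH and BRF1. The leading SW480 genes were NOG, UTS2R, BAIAP2L2, MYH13, MIR146A, ZNF420, IL12RB1, PTGIR, TMEM86A and TFAP2C. These counts carry no test of a single gene.

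NF-kB targets had a median line difference of −1.28 (LS180 minus SW480), which lay in the emetine pairs; none passed over all genes and 7 of 22 did when adjusted over the list alone (camera adjusted p = 5.46e-24; adjusted p = 0.527 with an estimated correlation). With emetine their median relative to all genes was 0.91 in LS180 and 3.44 in SW480, and with caffeine kept it was 0.22 in LS180 and 0.13 in SW480. CXCL1 (−3.47 ± 0.93) and TNF (−3.43 ± 0.83) had the largest differences. The cAMP and CREB targets had a median of −1.10, none past over all genes, and 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.000107; adjusted p = 0.607 with an estimated correlation). With emetine their median was 2.17 in LS180 and 4.39 in SW480, and with caffeine kept it was 0.68 and 0.50, the other way. Immediate early genes had a median of −0.40 and p53 targets of −0.34, with none past over all genes or adjusted over the list alone (camera adjusted p = 0.00098 and 0.0129; adjusted p = 0.527 with an estimated correlation for each). The medians of immediate early genes within each line were 2.43 in LS180 and 2.22 in SW480 with emetine and 0.93 and 0.86 with caffeine kept, and relative to all genes 2.26 and 2.45, and 1.14 and 0.80. Ribosomal protein genes and the stress response list each had a median of −0.23, with none past over all genes or adjusted over the list alone (camera adjusted p = 0.00699 and 0.0388; adjusted p = 0.925 with an estimated correlation for each); both calls were lost after quantile normalization.

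Genes with coding mononucleotide repeats often mutated in MSI tumours responded more in LS180, with a median line difference of 0.31 over 35 genes, against 0.06 for all genes. The shift lay mostly in the caffeine pairs: the median was 0.16 there, against −0.28 for all genes, and 0.52 against 0.42 with emetine. None passed over all genes or adjusted over the list alone (camera adjusted p = 0.00780; adjusted p = 0.527 with an estimated correlation). TGFBR2, the type II receptor of TGF-beta, differed by 2.92 ± 0.85 (adjusted p = 1.0); with emetine it was 2.79 in LS180 and −1.50 in SW480, and with caffeine kept 1.90 and 0.35. Another TGFBR2 probe set gave 0.67 and −1.38 with emetine, and 2.20 and −0.32 with caffeine kept. TAF1B (1.59 ± 0.74), BAX (1.19 ± 0.73) and TFAM (1.17 ± 0.77) followed. A further TAF1B probe set lay the other way with emetine, at −0.86 in LS180 and −0.01 in SW480, and gave −0.51 and −0.71 with caffeine kept. A further BAX probe set gave 0.45 and 0.15 with emetine, and −0.64 and −0.69 with caffeine kept. The other 19 lists gave adjusted p from 0.215 to 0.994.

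**Figure D3:**
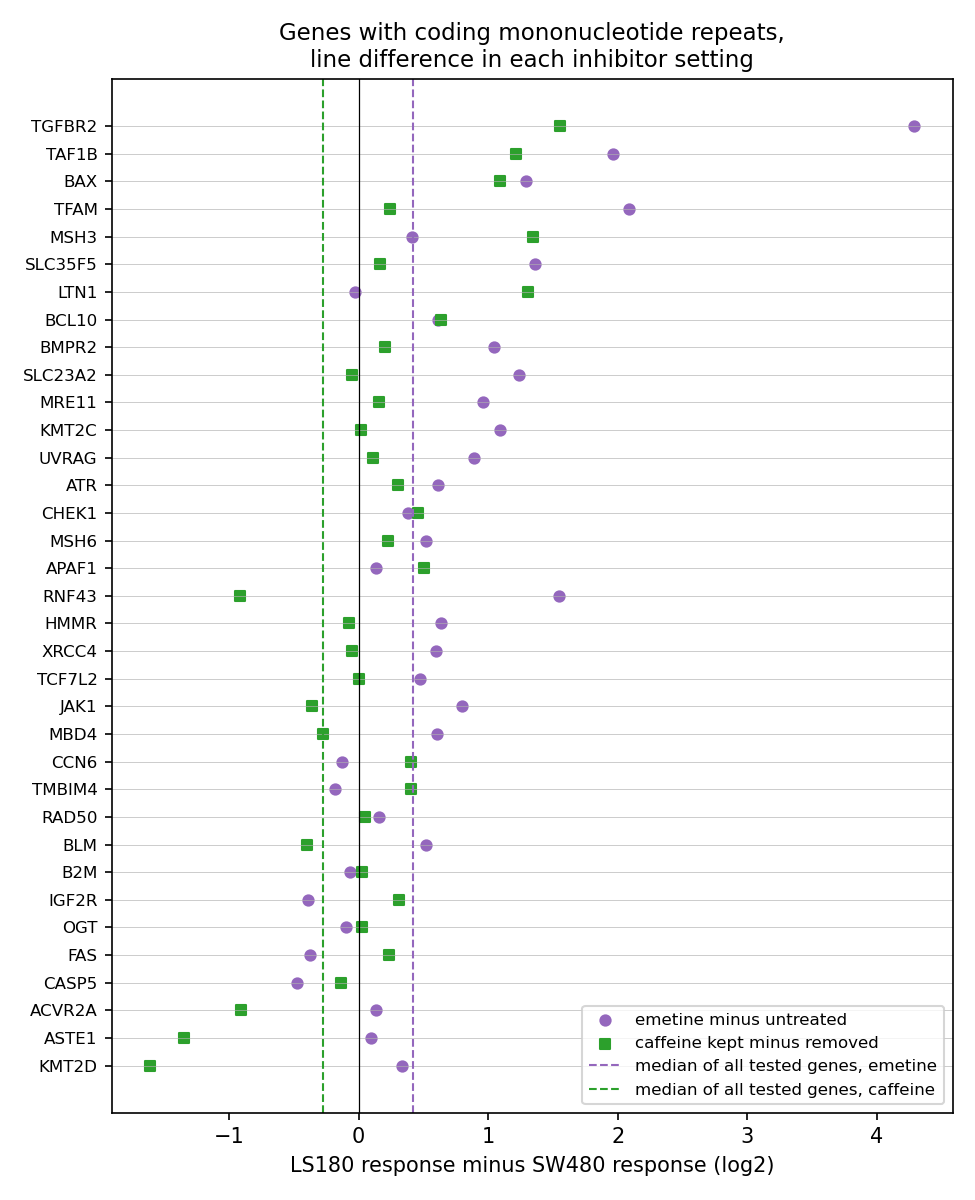
LS180 response minus SW480 response on the log2 scale for 35 genes with coding mononucleotide repeats, for emetine (circles) and caffeine kept (squares), with 1 array per group; dashed lines are the medians of all tested genes, 0.42 and −0.28. TGFBR2 lies at 4.29 and 1.55, and 17 genes lie above 0 in both settings and 1 below 0 in both.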

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

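Of the tests in this part, those of between-array scaling and of the hybridisation batch were chosen only after the result was seen.

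The poly-A control probe sets, which no comparison used, were 6.91-fold brighter in LS180 and 5.98-fold brighter in SW480 after caffeine and actinomycin D than on the untreated arrays. In the same comparison 220 genes fell and 4 rose. The actin control ratio was also higher on the untreated array of each line, which cannot be told apart from the treatment. Scaling as the whole cause is argued against by the centred arrays, where 100% of the 25 calls were falls, but scaling as a part stays open: centring moved the genes at least 2-fold changed in both lines from 78 higher and 778 lower to 295 and 461, and the median of all genes from −0.14 to 0.14. A hybridisation batch cannot be told apart from the treatment: the smaller poly-A ratio was 5.984, but no label names a batch, the hybridisation controls rose from 2400 to 4441 in LS180 and fell from 4959 to 3495 in SW480, and a lower share of mRNA under actinomycin D, not tested, would also brighten the poly-A controls. Loss of short-lived mRNA stays open as a hypothesis: the smallest gap of either short-lived list (immediate early, zinc finger) to either the reference or the ribosomal protein genes was −0.474 in LS180 and −0.844 in SW480, both beyond the 0.3 that its test asked for.

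The integrated stress response list stood at percentile 99.87 among matched random lists in LS180 and at 1.16 in SW480 after caffeine and actinomycin D, a difference that was not tested. The test of the line difference in the response to the inhibitors set 7 lists apart with camera's preset correlation and none with an estimated one. The adjusted p was 5.46e-24 for NF-kB targets, 0.000107 for cAMP and CREB targets, 0.00098 for immediate early genes and 0.00699 for ribosomal protein genes. It was 0.0078 for genes with coding mononucleotide repeats, 0.0129 for p53 targets and 0.0388 for the integrated stress response. When every probe set was tested, 2 probe sets without a single symbol were among the 19 called with emetine.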

How the results depend on the processing

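The setting as deposited, and the scalings of within-line counts, were chosen after seeing the data. With centred arrays the median of all genes after caffeine and actinomycin D turned from −0.14 to 0.14, and the medians of the integrated stress response and p53 lists over the 4 pairs from 0.04 to −0.02. No single gene tested under another scaling, pseudocount, filter, mean of its probe sets, variance model, threshold or block changed direction, though a further probe set of NACC2, TNFRSF10D, EREG, RYBP, ZBTB43 and ZBTB47 lay the other way: 2406 values of single genes or lists stayed on their side of the threshold, 417 no longer passed and 53 newly passed. The line difference of 4745 genes stayed within 1.5 times except for 8642 probe sets when every probe set was tested. Fewer arrays, fewer genes tested or another threshold account by construction for part of the following; otherwise the cause was not tested. Brightness limits what can be seen, since dim probe sets lie near the pseudocount.

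With emetine 46 genes passed; the count was 9 after quantile normalization, 7 with centred arrays, 7 as deposited, 8 with a pseudocount of 1, 121 with the median as pseudocount, 11 with no filter, 86 in the upper 25%, 19 for every probe set, 100 with trend and robust, 102 at 0.1, 0 with no replicate block and 519 in only the 4 arrays. For caffeine kept it was 1 with the median as pseudocount, 4 in the upper 25%, 1 with the mean of probe sets, 9 with trend and robust, and 257 in only the 4 arrays, against 0. After caffeine and actinomycin D it was 29, 25 and 44 under the 3 scalings in that order, 39 with a pseudocount of 1, 37 with no filter, 62 for every probe set, 344 with trend and robust, 457 at 0.1, 0 with no replicate block and 20 in only the 4 arrays, against 224. Over the 4 pairs it was 7, 2 and 5 under the 3 scalings, 2 with a pseudocount of 1, 91 with the median, 2 with no filter, 133 in the upper 25%, 14 with the mean of probe sets, 14 for every probe set, 187 with trend and robust, 43 at 0.1 and 0 with no replicate block, against 26. Leaving the pairing out as a block thus ended the calls of these 3 comparisons.

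Leaving out each array gave 1 to 111 genes with emetine, 0 to 1 for caffeine kept, 0 to 270 after caffeine and actinomycin D, 4 to 19 over the 4 pairs, 3663 to 4343 between the lines and 0 to 4 for the line difference in response. Without either array of the LS180 emetine pair, TGFBR2 with emetine turned to −0.17 (untreated left out) and −1.39 (emetine left out), in a range of −1.39 to 2.69 over all left-out arrays. Without either emetine array its difference between lines was −0.13 and that of NR4A2 in the response 0.60, the latter in a range of −5.51 to 0.60. None of these values had passed. Over the 4 pairs, between the lines and for the line difference in response, the 8 fits are 4 distinct ones. There, leaving out either array of a block gives the same fit. The same holds for the other comparisons when the array left out belongs to neither treatment compared.

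LS180-only and SW480-only genes by size numbered 56 and 22 with the median as pseudocount, 286 and 213 with no filter, 19 and 9 in the upper 25%, and 29 and 9 at 2-fold, against 95 and 50. The correlation of emetine between lines was 0.253 with no filter and 0.593 in the upper 25%, and that of caffeine kept 0.105 and 0.453. Emetine against caffeine kept gave 0.295 in LS180 and 0.262 in SW480 in the upper 25%. Genes at least 2-fold higher in both lines after caffeine and actinomycin D numbered 147 after quantile normalization, 295 with centred arrays and 143 as deposited, against 78, and 461 were lower with centred arrays, against 778. With an estimated correlation 0 lists passed in each of the 6 comparisons.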

Other observations

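In this part the exact interval of the ratio of SW480-only to LS180-only counts, the percentiles of the repeat list in each setting, its test without TGFBR2 the splits that part every pair or every treatment and the ratio of counts after re-pairing were chosen only after the result was seen.

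Wnt targets differed between the lines in both directions: LGR5, a stem cell receptor, was higher in LS180 by 4.66 ± 0.34 on the log2 scale, and TNFRSF19 and LEF1 were lower by −4.65 ± 0.35 and −4.46 ± 0.39. Of 20, 6 were higher and 11 lower, the same when adjusted over the list alone (camera adjusted p = 0.0964). Of 10 mismatch repair genes, MSH6 and PCNA were lower in LS180, at −1.44 ± 0.27 and −1.22 ± 0.28, and 2 when adjusted over the list alone (camera adjusted p = 0.386). Genes with coding mononucleotide repeats were lower in LS180 in 12 of 35 and higher in 4, and likewise when adjusted over the list alone, with CCN6 at −2.46 ± 0.30, LTN1 at −1.93 ± 0.35 and TMBIM4 at 1.78 ± 0.27 (camera adjusted p = 0.0678).

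Of the 32 splits of the 8 arrays into 4 and 4 that could be fitted, 1 gave as many genes as the line difference, the real one with 4745 against 0 in the highest other. The fit compares lines within treatments. Of the 8 splits that part the lines in every treatment, the real one had 4745 and the highest other 0. That is too few splits for a share under 0.05. Every other split leaves the line difference in the residual spread, so counts of 0 there decide nothing. Over the 4 pairs of inhibitor and comparison arrays 3 splits gave as many, so chance cannot be excluded by that count. The real split had 26 and the highest other 161. The splits with 161 part the emetine arrays from the untreated ones in both lines and part neither caffeine pair. With the pairs as blocks they are the same fit, of emetine against untreated. That is a treatment comparison, so its count does not measure chance. Among the 8 splits that part every pair, too few for a share under 0.05, the real one had 26 and the highest other 0. The other splits of that kind leave the shared response in the residual spread, so their counts decide nothing either.

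The 38 genes that rose with emetine could reflect transcripts stabilised by NMD inhibition. The test of a general change in scaling decides little. The arrays had been scaled to a common median, and the 38 genes were picked for large rises. The higher of both lines' ratios of the median change of reference and ribosomal protein genes to the median rise was −0.03274, under the bound set in advance. Of the 46 genes called with emetine, 7 passed with centred arrays, 7 as deposited and 9 after quantile normalization. With caffeine kept, the 38 genes stood at percentile 100 of matched random lists in both lines, with medians of 0.81 in LS180 and 0.91 in SW480. Induction of stress genes by both drugs was not tested and stays open. The actin control ratio, higher on the untreated than on the emetine array in each line, cannot be told apart from emetine here.

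The search for LS180 transcripts kept by NMD inhibition gave 95 LS180-only genes, within the 80 to 113 found after re-pairing the settings, so chance agreement of the settings may account for the number. The SW480-only count of 50, within 31 to 53 after re-pairing, was 0.5263 times as large. That ratio lies under the bound set in advance, by which array noise would have been argued against. The exact interval, chosen later, ran from 0.366 to 0.749, across that bound. It treats genes as independent and measures no spread between arrays. The means after re-pairing give 0.437, so the ratio follows how many genes pass each setting and leaves array noise open. With arrays centred on the tested genes, the counts were 86 LS180-only and 56 SW480-only. The repeat list lay higher in the LS180 response (camera adjusted p = 0.007804), the outcome set in advance for frameshifted transcripts kept on NMD inhibition, which is consistent with that hypothesis; requiring an estimated correlation as well (adjusted p = 0.527) would have left it undecided. Its line difference stood at percentile 99.99 of matched random lists with caffeine kept but at 77.2 with emetine, and the unadjusted camera p went from 0.0015 to 0.0102 without TGFBR2. Whether these transcripts carry frameshifts was not analysed here.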
